A study of Drosophila melanogaster with 4 samples.

How the data were processed

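The series profiled histone H3, a core protein of every nucleosome, by chromatin immunoprecipitation and sequencing (ChIP-seq) in heads of wild-type Oregon-R Drosophila melanogaster. There were 4 libraries. An antibody named only as H3 antibody3 gave 2 ChIP libraries, and 2 Input libraries served as their references, one per replicate, per the labels. Per the labels' protocols, adult flies came from population cages kept on a 22-day cycle and heads were separated from bodies with sieves. Nuclei were fixed with formaldehyde, lysed with SDS and sonicated, and the chromatin was incubated with antibody for 15 hours. Nothing in the labels says whether the replicates came from separate cages, so differences between them may be partly technical.

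Per the file headers, all coordinates are on FlyBase release 5. Bowtie 0.12.7 is named in the submitters' processing notes, per the labels. The region caller, its threshold, the treatment of multiply mapping reads and the depth of sequencing are not given in the sources used here. The authors deposited 3 lists of regions of significant enrichment: 1 per ChIP replicate and 1 for the replicates together, called the combined list here. How the replicates were joined for the combined list is not given. Each line gives a start, an end and the authors' deposited score, whose scale and log base are not stated. The score was used to describe, rank and filter regions within its own list, and in 1 description was correlated between overlapping regions of the replicate lists. No read counts or coverage values were at hand, so depth is unknown, no counting interval is given, and the Input libraries enter only through the authors' calling.

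Per the file headers, 14 sequences make up the reference: the major arms 2L, 2R, 3L, 3R and X, chromosome 4, the heterochromatic sequences 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, and the unplaced sequences U and Uextra. Uextra held no region in any list, and shares of the genome were taken over the other 13. In the combined list 2 regions ran past the sequence end given in the header and were shortened to it. In the replicate lists 0 did.

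Regions were counted and their bases summed per list and per sequence. The replicate lists were compared by the share of regions meeting a region of the other list by at least 1 bp and by the Jaccard index of bases in 50 bp bins. Both were set against 100000 circular shifts of the replicate 2 list, drawn independently within each sequence, which keep region lengths and spacing. These permutation tests were one-sided, and the smallest p they can give is 1e-05. The test asks whether regions coincide more than shifted regions do. It does not measure variation between flies. The observed replicate 1 list on the major arms (2223 regions) was also set against simulated lists of about the replicate 2 list's size. There were 40 simulations per setting, with 2000 shifts each. The excess over shifts was expressed as a percentage of the share that the shifted mean left unmet. A planted overlap of 0%, 5%, 10% and 20% gave a mean excess of 0.066%, 4.56%, 9.35% and 19.0%. With nothing planted, 2.5% of simulations had p under 0.05, and each planted setting had 100%. The simulated regions had 1 fixed length and were placed evenly along the arms, without the regional density that the replicate lists share. The error rate of the shift test under shared regional density was therefore not tested.

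Enriched bases per sequence were compared with sequence length, with no test, because each library gives 1 value per sequence. Score differences and coverage ratios above a common score have 95% intervals from 10000 bootstrap draws of regions, which treat regions as independent. For chromosome 4, the limit needed is the lowest score down to which autosomal-arm regions cover no more of the arms than regions cover of chromosome 4, drawn anew in each bootstrap draw. The covered share of 1 Mb windows and of the centromere-proximal 2 Mb of each major arm was examined after the region lists had been seen, as was overlap within classes of 25% of regions by length and by score. Regions were named by a rule fixed before the data were examined: the 10 combined-list regions with the highest score and the 10 longest. The same plan held tests of annotation classes, transcription start sites, GC content and 21 gene lists. These were not analysed, since the only gene table at hand is on release 6 and coordinates were not converted between releases. Regions are therefore given by position, without gene, exon or intron. Alternatives were a stricter score limit (the median of each list), length limits of 200 bp and 1000 bp, merging of regions closer than 500 bp, the major arms alone, stricter overlap rules (50% of both regions, 25% of the shorter), 100 random placements with bedtools 2.31.1, single-base resolution, and each replicate list in place of the combined one. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.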

Results

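Enrichment of histone H3 over Input chromatin was mapped in adult fly heads with 1 antibody in 2 ChIP replicates, each with its own Input. The data are lists of enriched regions on FlyBase release 5. The replicate 1 list held 2327 regions and the replicate 2 list 2779 (2553 ± 319.6, SD, n = 2). They covered 3.70 Mb and 4.48 Mb (4.09 ± 0.552 Mb), or 2.65% and 3.21% of the sequences that carried regions. The combined list, which the authors deposited for the replicates together, held 16757 regions over 27.3 Mb, 19.5% of the same sequences. It was 6.56 times as long as the mean replicate list by number and covered 6.67 times as many bases. Read depth was not at hand, so the precision that depth gives to any single region is unknown.

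Enriched regions were short and of similar size in the replicates. The median length was 1493 bp in replicate 1 and 1507 bp in replicate 2, with the middle 50% of regions between 1379 and 1711 bp and between 1381 and 1744 bp. In the combined list the median was 1422 bp and the longest region 10932 bp. No listed region was shorter than 1301 bp in either replicate list or 1001 bp in the combined list, so the lists show no feature of the size of a single nucleosome. The replicate lists share their shortest length, and the combined list has another. Whether the similar sizes in the replicates come from the calling was not tested. The authors' scores, whose scale is not given, had medians of 0.581 and 0.602 in the replicates and 0.415 in the combined list.

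The first comparison asked how far H3 enrichment was shared between the replicates. Of the replicate 1 regions, 445 (19.1%) met a replicate 2 region, and of the replicate 2 regions 440 (15.8%) met a replicate 1 region. On 2R 126 of 522 replicate 1 regions (24.1%) met one of replicate 2, and on X 21 of 198 (10.6%) did. Relative to shifts within the same arm the share was 2.57 times the shifted mean on 2R and 2.91 times on X, with 2.59 on 2L, 2.94 on 3L and 2.15 on 3R. On the unplaced sequence U 11 of 48 (22.9%) met a replicate 2 region, 15.1 times the shifted mean. That mean was 1.52% ± 1.83 (SD over shifts), so the ratio is imprecise and not comparable with those of the arms. On the Het sequences 7 of 26 met one on 3RHet, 1 of 11 on 2RHet, 1 of 12 on 3LHet and 0 of 3 on 2LHet. On chromosome 4 it was 0 of 2. Circular shifts gave 7.37% ± 0.548 (SD over shifts) for replicate 1 regions and at most 11.5%, so the observed share was 2.59 times the shifted mean (one-sided permutation test, p = 1e-05, the smallest the draws can give). The Jaccard index of bases was 6.68%, against 1.74% ± 0.152 under shifts (one-sided permutation test, p = 1e-05). Shifts do not keep the regional density that the replicates share along the arms. How much of the excess comes from that density was not tested.

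**Figure D1:**
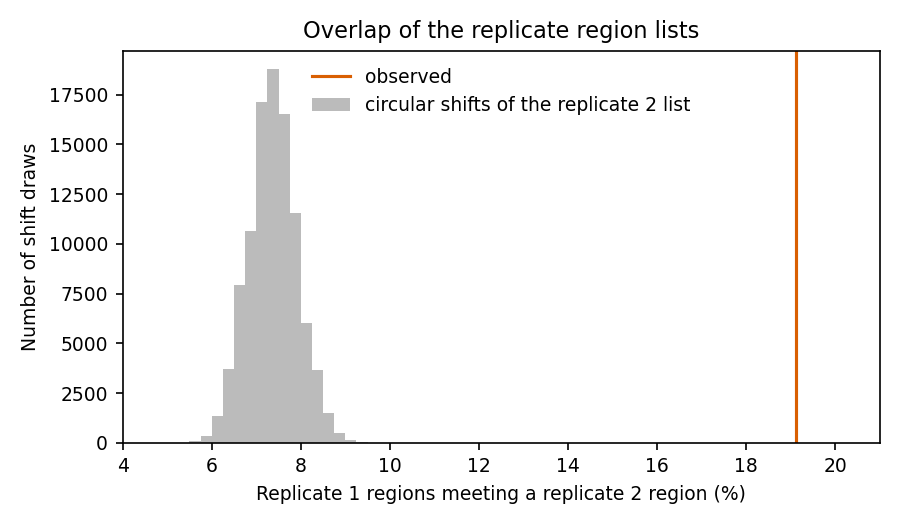
The x axis is the percentage of replicate 1 regions that meet a replicate 2 region by at least 1 bp, and the y axis is the number of circular-shift draws in each 0.25 percentage-point bin. The observed 19.1% (vertical line) lies above the highest of the 100000 shifts, 11.5% (grey bars centred on 7.37%).

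The share of regions that recurred is given here by length and by score. In the longest 25% of replicate 1 regions (1711 to 5047 bp) 27.3% met a replicate 2 region, 3.28 times the shifted mean for those regions. In the shortest 25% (1301 to 1379 bp) 14.8% did, 2.20 times. In replicate 2 the shares were 22.0% (3.11 times) and 12.1% (2.17 times). By score, the shares in replicate 1 were 17.2% in the lowest 25% of scores (2.25 times the shifted mean) and 19.2% in the highest 25% (3.15 times). In replicate 2 they were 16.7% (2.63 times) and 14.8% (2.76 times). Each of these 25% classes exceeded its shifts (one-sided permutation tests, p = 1e-05 in each of 16 classes, Benjamini-Hochberg adjusted p = 1e-05), but the differences between classes were not tested. Over the 452 overlapping pairs of regions, scores of the replicates correlated with a Pearson r of 0.627 and a Spearman rho of 0.443. Pearson r was 0.503 without the 2 pairs farthest from the median. On the major arms alone (432 pairs) r fell to 0.477 and rho to 0.409. With a reciprocal overlap of at least 50% (316 pairs) r was 0.635 and rho 0.506. This correlation is across regions, which are not independent replicates.

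The combined list took in nearly all regions of the replicates and many more. Of replicate 1 regions 96.4% met a combined region, and of replicate 2 regions 96.5%, with 92.5% and 92.2% of their bases inside it. This describes the lists, since the combined list was made from the same libraries. Of the combined regions, 469 (2.80%) met both replicate lists, 1746 met replicate 1 only, 2208 met replicate 2 only, and 12334 (73.6%) met neither. Those meeting both had a median length of 2747 bp and a median score of 0.457. Those meeting neither had a median length of 1290 bp and a median score of 0.414. The regions found by neither replicate held 65.2% of the combined bases.

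The second comparison was between chromosomes. The major autosomal arms 2L, 2R, 3L and 3R carried the densest H3 enrichment, with 23.9% of their bases in combined regions and 3.67% ± 0.476 (SD, n = 2) in replicate regions. The right arms were more densely covered than the left arms: 26.4% of 2R and 26.5% of 3R lay in combined regions, against 21.1% of 2L and 21.3% of 3L. The right-to-left ratio was 1.34 in replicate 1, 1.41 in replicate 2 and 1.25 in the combined list. The direction was the same in both replicates, with a replicate mean of 1.38 ± 0.049. With 1 value per library and 2 libraries, no test between arms was made.

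The X, which males carry as a single copy, was covered more sparsely than the autosomal arms. Its covered share was 1.38% and 1.84% in the replicates (1.61% ± 0.328) and 12.7% in the combined list, and in each list it lay below every major autosomal arm. The ratio of X to autosomal arms was 0.415, 0.460 and 0.534 in replicate 1, replicate 2 and the combined list. Regions on X had higher scores than autosomal regions in the same lists, with medians of 0.744 against 0.568, 0.737 against 0.590 and 0.517 against 0.404. Among combined regions at or above the list's median score, the share of enriched bases on X was 1.20 times its share of length, against 0.653 over all regions. X then lay above 2L, 3L and 3R (0.917, 0.930 and 1.14) but still below 2R (1.23). Scores are higher on X, so this limit keeps more of its regions.

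Chromosome 4, a small and largely heterochromatic autosome, had the lowest coverage of any sequence in the combined list. It carried 22 combined regions over 2.32% of its length, 0.0971 times the autosomal-arm share, and 2 and 3 regions in the replicates (0.276% ± 0.0675 of its length). The pericentric heterochromatin sequences 2LHet, 2RHet, 3LHet and 3RHet together had 8.11% of bases in combined regions, 0.339 times the autosomal arms, and 1.16% ± 0.239 in the replicates. Among them 3RHet was the densest, at 10.2% in the combined list and 1.96% ± 0.228 in the replicates. XHet carried 4 combined regions and YHet 7. XHet had none in either replicate, and YHet had 2 in replicate 1 and 0 in replicate 2. The unplaced sequence U carried 389 combined regions over 5.81% of its length, at a median score of 0.854.

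**Figure D2:**
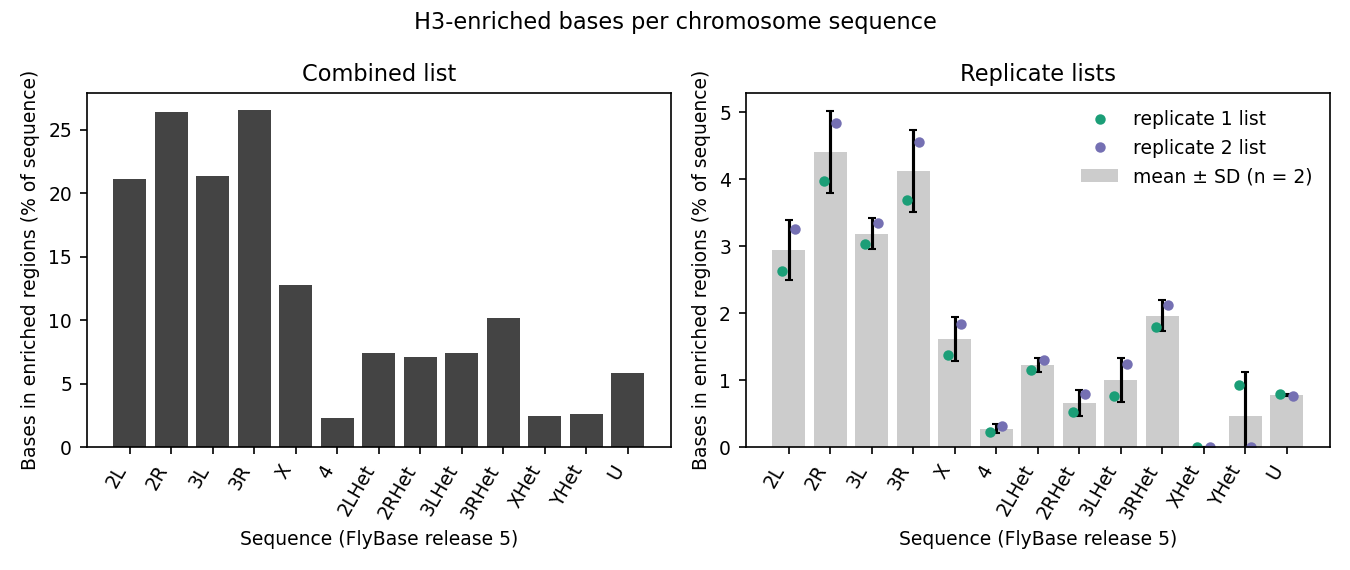
The y axes give bases in enriched regions as a percentage of each sequence for the combined list (left) and the replicate lists (right, points for each replicate, bars for the mean and error bars for the SD, n = 2). The arms 2R and 3R stand highest in both panels, at 26.4% and 26.5% in the combined list, X is at 12.7% and chromosome 4 at 2.32%.

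The highest scores and the longest regions lay in different parts of the genome. The 10 combined regions with the highest scores, 3.40 to 4.08, were 1010 to 1181 bp long. Of these 8 were on U and the others on 2RHet, and 0 met a region of either replicate list. The top 1 spanned U 7201022 to 7202104. The 10 longest combined regions, 7527 to 10932 bp, were all on major arms, with scores of 0.391 to 0.524. Replicate 1 met 7 of them and replicate 2 met 9, and 7 were met by both. Over all combined regions 13.2% met replicate 1 and 16.0% met replicate 2. Longer regions have more bases with which to meet one, and no expectation matched on length was computed for these 10. The longest, 2R 3228828 to 3239759, met 3 replicate 1 regions and 1 replicate 2 region. The region 3R 25531187 to 25541336 (10150 bp) met 2 of each. Regions at 3R 12202220 to 12210465 (8246 bp), 3R 22508324 to 22517192 (8869 bp) and 2L 3608405 to 3617002 (8598 bp) were also met by both replicates. Scores over 1 were given to 44 regions in replicate 1, 39 in replicate 2 and 260 in the combined list. Of these 81.8%, 84.6% and 81.2% lay outside the major arms, which held all but 4.47%, 4.35% and 5.25% of regions.

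**Figure D3:**
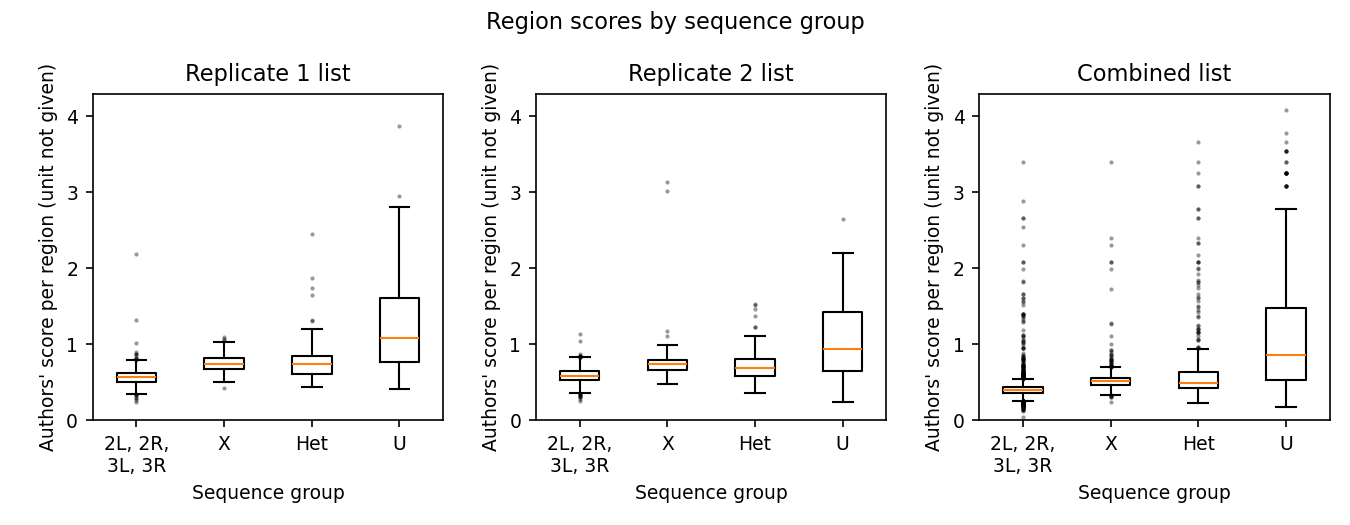
The y axis is the authors' score per region and the x axis groups regions by sequence (the autosomal arms, X, the 4 pericentric Het sequences and U). Boxes span the middle 50% with the median as a line, whiskers reach 1.5 times that span and points are regions beyond. In the combined list the median is 0.404 on the autosomal arms, 0.517 on X, 0.495 on the Het sequences and 0.854 on U.

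At the scale of 1 Mb windows the replicates had similar landscapes along the arms. Over 117 windows of the major arms, the covered share in replicate 1 and replicate 2 correlated with a Pearson r of 0.834 and a Spearman rho of 0.844. Shifting windows within arms gave a mean r of 0.374, which reflects differences between arms (one-sided permutation test, p = 1e-05 for r and for rho). Within arms, r was 0.874 on 2L, 0.704 on 2R, 0.802 on 3L, 0.681 on 3R and 0.513 on X. In each arm the true alignment gave the highest r and rho of all shifts, with exact one-sided p-values of 0.037 to 0.0476, which are the smallest that 21 to 27 windows allow (Benjamini-Hochberg adjusted p = 0.0476 in each arm). The densest combined windows were 2R 20000001 to 21000000 (38.5%), 2R 19000001 to 20000000 (36.4%) and 3R 25000001 to 26000000 (35.9%). The sparsest were X 12000001 to 13000000 (7.89%), 3L 23000001 to 24000000 (7.95%) and 2L 21000001 to 22000000 (8.21%).

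**Figure D4:**
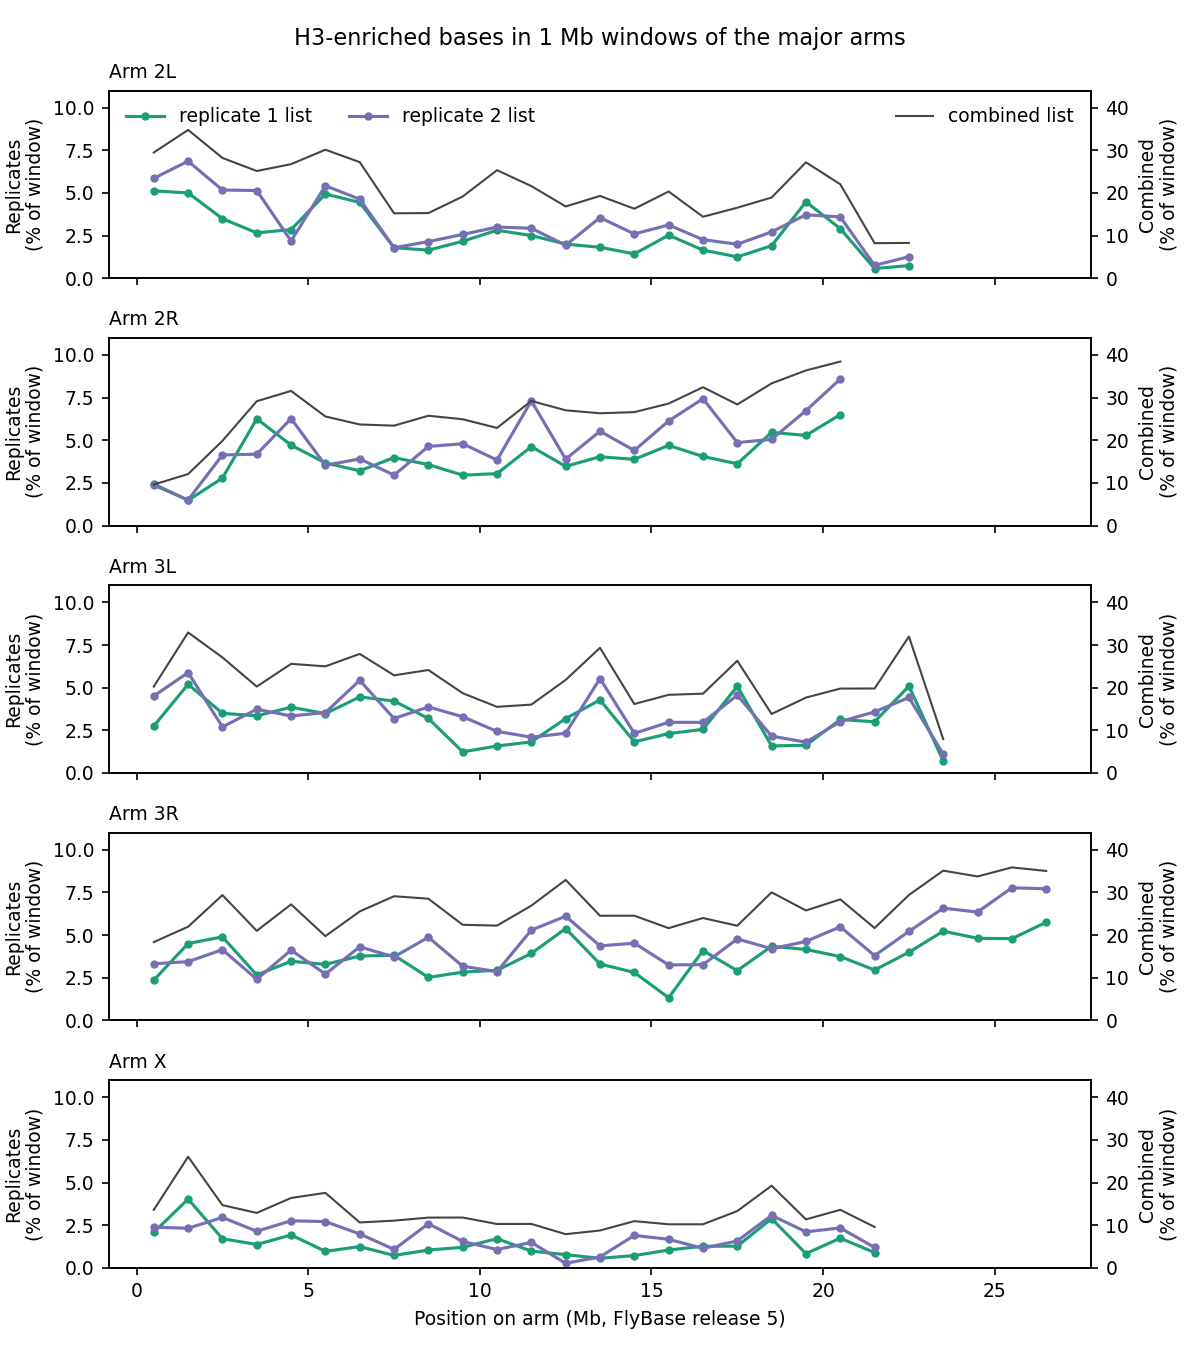
For each major arm, the left axis gives the percentage of each 1 Mb window in replicate 1 and replicate 2 regions and the right axis, on a different scale, that in combined regions, against position in Mb. The replicate lines follow each other (r = 0.834 over 117 windows), and coverage is low at the right end of 2L and 3L and at the left end of 2R.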

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

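The excess of replicate overlap over shifted or randomly placed regions held under all alternatives run. Neither kind of placement keeps the regional density that the replicates share along the arms. The alternatives therefore do not separate recurrence of single regions from that shared density. The share of replicate 1 regions meeting replicate 2 ranged from 12.96% (regions at or above the median score) to 19.1%. The one-sided permutation p was 1e-05 under shifts and 0.0099, the smallest possible, under 100 random placements. At or above the median score the shifted mean fell as well, from 7.37% to 3.58%. The share was then 3.62 times the shifted mean, against 2.59 over all regions. That ratio ranged from 2.51 (major arms alone) to 4.08 (reciprocal overlap of at least 50%). Keeping regions at or above the median score left 1165, 1390 and 8381 regions over 1.92, 2.34 and 13.8 Mb in the replicate 1, replicate 2 and combined lists, by construction. The 200 bp limit removed no region. Merging regions closer than 500 bp left 2276, 2730 and 14545 regions in the replicate 1, replicate 2 and combined lists. It raised the median length in the combined list from 1422 to 1510 bp. On the major arms alone the combined list covered 25.9 Mb. A reciprocal overlap of 50% lowered the share of replicate regions in the combined list to 80.1% and 81.0%, and the median-score limit lowered it to 75.3% and 73.8%.

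Enriched share over length share is above 1 where a sequence holds more than its part. In the combined list it was 1.08 on 2L, 1.35 on 2R, 1.09 on 3L, 1.36 on 3R, 0.653 on X, 0.119 on 4, 0.298 on U and 0.415 on the 4 Het sequences. With one replicate list alone it was 0.995 (replicate 1, reversed) to 1.02 on 2L, 1.50 to 1.51 on 2R, 1.39 to 1.42 on 3R, 0.521 to 0.575 on X, 0.0861 to 0.101 on 4, 0.240 to 0.298 on U and 0.374 to 0.414 on the Het sequences. Over bases shared by both replicate lists it was 0.894 on 2L (reversed), 1.82 on 2R, 1.17 on 3L, 0.276 on X, 0 on 4 and 0.419 on U. At or above the median score it was 0.917 on 2L and 0.930 on 3L (both reversed), 1.23 on 2R, 1.14 on 3R, 1.20 on X (reversed), 0.535 on U and 0.631 on the Het sequences. The cause was not tested, except that scores on X, U and Het are higher than on the autosomal arms, so this limit keeps more of their regions. The side of 1 on which 2L and 3L fall thus depends on the list or limit, whereas 2R and 3R stayed above 1 and chromosome 4 below 1 in each alternative. The alternatives set out for annotation classes, start sites, GC content and gene lists were not run, for want of a release 5 annotation. No paired analysis was possible because the Input libraries have no values of their own in the files used here. Depth is unknown, so regions absent from a replicate list are not shown to lack enrichment.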

Other observations

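The tests on median score by sequence, on the low scores of chromosome 4, on the score's scale, on the Het sequences at a common score, on a higher limit over the same scores and on shuffles matched on less than sequence and length were chosen after the result was seen. The tests of the X ratio at a common score, of the shared combined regions and of the arm ends had their outcomes set down before they were run.

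Among the major arms, long stretches without any combined region marked a few places. The longest was 2L 21400897 to 21592416, 191520 bp, in which the replicate lists together held 1558 bp. A second gap on the same arm, 2L 21598000 to 21705616, lay just beyond it. The next longest were 2R 2173264 to 2310633 (137370 bp), X 22964 to 138541 (115578 bp), X 15879486 to 15993319 (113834 bp) and 3L 23104149 to 23215468 (111320 bp). Replicate regions held 69 bp of the first X gap and 0 bp of the other three. Neighbouring combined regions were otherwise 3086 bp apart at the median, and 77 gaps exceeded 50 kb. These gaps were chosen after their values were seen. Whether reads can be placed there was not analysed.

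Coverage next to the centromere was lower than elsewhere on some arms, though no arm passed correction. In the proximal 2 Mb the combined list covered 8.24% of 2L, 10.9% of 2R and 12.1% of 3L, against 22.4%, 28.0% and 22.2% of the rest of each arm. These 3 of the 5 arms lay below the central 95% of circular shifts in the combined list, against the outcome set down for an even spread. In each replicate list only 2L and 2R did, and 3L lay inside (p = 0.2503 and 0.162, two-sided permutation test). The values for 3R (20.2% against 27.0%) and X (10.2% against 12.99%) did not. The two-sided permutation p-values were 0.0201, 0.0145 and 0.0463, and 0.0755, 0.0755 and 0.0992 after Benjamini-Hochberg adjustment over 15 tests (5 arms in 3 lists), all above 0.05. On 3L the low value lies at the very end of the arm: the window 22000001 to 23000000 was 32.0% covered and the next one 7.95%, which is no gradient. The proximal value was below the rest in all 5 arms of both replicate lists. A lower density beside pericentric heterochromatin is a hypothesis, and fewer placeable reads there could give the same picture.

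The sparse coverage of X goes with higher scores. The combined median score on X exceeded that of the autosomal arms by 0.113 (95% bootstrap interval over regions, which are not independent, 0.107 to 0.117), and the median was higher on X in all 3 lists. At or above the 75th percentile of X scores in each list, X was 23.4, 9.04 and 12.9 times as densely covered as the autosomal arms in replicate 1, replicate 2 and the combined list. A higher score limit for calls on X, acting on the same distribution of scores, would leave a ratio near 1 there. The lowest 95% bootstrap bound was 5.92, which argues against such a score limit as the whole cause. The calling threshold is not given, and combined scores on the autosomal arms reach down to 0.0501. A limit on a quantity other than the score was therefore not tested. The outcome set down beforehand for a higher score needed on X was a ratio of 1 or more in all 3 lists, and it was met. That outcome cannot decide the question, since upward-shifted scores on X alone set the ratio above 1. The ratio of 9.04 therefore gives no separate support for a limit combined with upward-shifted scores. Fewer reads on X, which could both raise the limit and widen the scores, and a difference in H3 occupancy stay open, because depth is unknown and the labels give no sex.

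On the 4 Het sequences the combined median score exceeded that of the autosomal arms by 0.0915 (95% bootstrap interval 0.0760 to 0.110). At or above the 75th percentile of Het scores they were 21.6, 8.76 and 16.8 times as densely covered as the autosomal arms in replicate 1, replicate 2 and the combined list. The lowest bootstrap bound was 4.69, which argues against a higher score limit over the same distribution of scores as the whole cause. As for X, a limit on a quantity other than the score was not tested. Fewer placeable reads and a lower density of enriched sites stay open. On chromosome 4 the combined median score differed from that of the autosomal arms by -0.0142 (interval -0.0497 to 0.0749, 22 regions). The replicates went opposite ways, by 0.236 and -0.0804, from 2 and 3 regions. The 5th percentile of scores differed by 0.261 and 0.0363 in replicate 1 and replicate 2 and by 0.000955 in the combined list (interval -0.0131 to 0.0367). To cut the coverage of the autosomal arms to that of chromosome 4 in the combined list, the limit would have to be a score of 0.475. Of the 22 regions 15 scored below it (68.2%, interval 45.5% to 86.4%). This argues against a higher score limit over the same distribution of scores as the whole cause, in the combined list only. In replicate 1, 1 of 2 regions scored below its limit (interval 0% to 100%), and in replicate 2, 3 of 3 did, too few to decide. A limit on a quantity other than the score was not tested here either. With so few regions, a higher limit over other scores, fewer placeable reads and a lower density of H3-enriched sites cannot be told apart.

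The replicate lists were also set against the combined list as a pool. Regions were matched on sequence, with all sequences outside the major arms pooled, and on length in 10 bins. If each list were a random draw of combined regions so matched, 628 regions (95% of shuffles 595 to 662) would meet both lists. The observed number was 469 (two-sided permutation test, p = 2e-05, the smallest the draws can give). Matched on sequence only, the shuffles gave 359 (328 to 391), and with no matching 354 (323 to 385), and 469 is then an excess (two-sided permutation tests, p = 2e-05 each). The sign therefore depends on matching by length, and none of these random draws gives the observed number. How the combined regions were built is not given in the sources used here, so the reason for the change of sign was not tested. The pool was made from the same libraries, and its regions meeting both lists were longer than those meeting neither (medians 2747 bp and 1290 bp). Membership and length in the pool may thus depend on the replicates themselves. These shuffles therefore do not measure how well the replicates agree.

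The highest scores repeat a few values. Taken as powers of 2 relative to the top score, the 12 highest combined scores are fractions with the common denominator 16, namely 16, 13, 12, 11 and 10 sixteenths (tolerance 1e-06), while bases e and 10 gave no common denominator up to 50. This is consistent with scores that are log2 of a ratio in which the largest values rest on small whole numbers, and would make the median scores 1.33-fold in the combined list and 1.50-fold and 1.52-fold in the replicates. Such values on U and 2RHet would then be among the least precise in the list. The authors' definition was not used here.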
